A study of Mus musculus with 33 samples.

How the data were processed

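RNA of 33 mouse libraries in 11 groups of 3 was sequenced: Smart-Seq2 libraries of sorted tuft and non-tuft epithelial cells from KC pancreas and wild-type intestine, and stranded TruSeq libraries of cultured BMM and mPSC. Tuft cells were sorted with antibodies to EpCAM and Siglec F, with Cd45 as a further label, 100 cells per library. Each tuft library came from 1 mouse. Stellate cells came from pancreata pooled over 2 or 3 mice. The mPSC labels mention at least 3 biological replicates per experiment without saying what was kept separate, and the BMM labels mention none. Nothing says that the 3 libraries of such a group came from separate animals or cultures, so their p-values measure only the spread between these libraries, which may be technical. Per the labels, the authors' processing used FastQC, HISAT2, StringTie, limma and the mm9 assembly, without versions. The gene annotation at hand was for another build, so no coordinates are given and genes are named by symbol.

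The authors deposited 5 tables, whose values per library are log2 expression values, per the file headers and the range of the values. Which abundance was logged, and what was added before the log, is not stated. The deposited ratio columns of the tuft and mPSC tables hold the linear fold change of the second group over the first. Their p-value and adjusted p-value columns, per the file headers, come from a test that is not named. Recomputing them with limma without a variance trend gave the deposited p-values of the tuft tables without a replicate block, and those of the mPSC tables closely with the replicate number as a block. Counts and depths are in no table, so the depth per library is unknown and no interval from counting could be given.

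Values of the tuft and BMM tables had been quantile-normalised (largest gap between libraries at one rank 0.54 in the pancreas, 0.15 in the intestine, 0 in BMM) and have a minimum of 0. Zeros made up 16.3%, 15.2% and 1.48% of these 3 tables. The mPSC tables hold no 0 and had been adjusted per replicate number: deviations of same-numbered libraries from their group means correlated at -0.998 to -0.94 in the PGE2 and -0.991 to -0.91 in the PGD2 table. The vehicle libraries had slightly different values in both mPSC tables (SD of the difference 0.122 to 0.152 per library over 7246 genes, 0.018 for the means), so these tables were fitted separately. A symbol that occurred again in a table, 1 in each, kept its name for the entry with the higher mean. Symbols turned into dates by a spreadsheet (14 to 16 per table) were kept and none is named.

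Each comparison was fitted with limma 3.58.1 in R 4.3.3 (eBayes with a variance trend) on the deposited log2 values, without covariates. Genes had to exceed 1 on the log2 scale in at least 3 libraries of the fit. The Benjamini-Hochberg adjusted p had to be under 0.05 over all genes tested: 10112 in the pancreas, 9359 in the intestine, 8915 in BMM, 7108 and 7111 in the PGE2 and PGD2 tables. The spread was pooled over 6 libraries in each tuft or mPSC fit and over 12 in BMM. Differences of effects were tested as contrasts of one fit, over the 8318 genes tested in both tissues or the 8915 of BMM. PGE2 and PGD2 effects were compared in limma by the difference of both effects within each replicate number, over 7066 genes, with 95% intervals. This test was added after the values were seen, since the plan gave only values where the tables had been processed separately.

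Replicate numbers are shared between groups. In BMM, deviations of same-numbered libraries correlated at 0.239 to 0.605, all above the minimum of 0.1 set for pairing, so the numbers pair the libraries. Fits were run without and with the replicate number as a block. For mPSC the words rose and fell rest on the blocked fit. On simulated data with the same adjustment, the fit without a block called 323 and 294 unchanged genes and the blocked fit 6 and 5. The mPSC SE (of the fit without the block), SD and correlations understate the spread, part of which was adjusted away. The other fits, tested on simulated data with 200 changed genes, called 2 to 12 unchanged genes.

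In all, 38 gene lists were fixed beforehand, and members past the gene-wise threshold were counted over all genes and adjusted over the list alone. Lists with at least 5 members tested were also tested with camera of limma, with a preset correlation of 0.01, adjusted over the lists of a comparison. Of 128 list tests 52 passed, and 5 passed with an estimated correlation, namely tuft markers in the intestine, proliferation genes in 3 BMM tests (PGD2, LPS and the difference of the PGD2 effects) and NRF2 targets with PGD2 in resting BMM. Erythroid genes in the tuft tables and dendritic and lymphoid markers in BMM had 0 members past the filter. Named genes followed a rule: per comparison the 8 largest rises and 8 largest falls among genes past the threshold whose groups did not overlap (4 each way for differences of effects), up to 4 members per list with the smallest p, all members of the synthesis and receptor lists, and the sort genes Epcam, Ptprc and Siglecf. Unnamed gene models were left out. Non-overlap is expected by chance for 10% of genes with 3 against 3 libraries. Groups, tests, lists, the naming rule and the first set of alternatives were fixed before the data were examined.

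Alternatives were no filter, a minimum of 5, sample weights, the replicate block, a fold change of at least 2, adjusted p under 0.01, quantile normalization (mPSC), fits of the compared groups alone, and leaving out each library. Added later were fits without a variance trend, blocked fits leaving out a replicate number, combinations with the block, and the overlaps of tuft calls between tissues and of PGD2 calls between BMM and mPSC. Calls were also counted in other splits of the same libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Sequencing reads were not reprocessed, and no sample was left out.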

Results

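Gene expression was measured by bulk RNA sequencing in 33 mouse libraries, which form 11 groups of 3. Tuft cells, rare chemosensory cells of epithelia, and other epithelial cells were sorted from the pancreas of KC mice aged 8 to 10 months, in which Ptf1aCre switches on a mutant Kras allele, and from the proximal small intestine of wild-type mice aged 12 months. Each tuft library came from 100 cells of 1 mouse. Bone marrow-derived macrophages (BMM) were given prostaglandin D2 (PGD2, 10 µM) or its vehicle, methyl acetate, for 24 h, with or without lipopolysaccharide (LPS, 100 ng/ml, added 4 h earlier). Pancreatic stellate cells (mPSC), the fibroblast precursors of the pancreas, were activated in culture and kept with PGE2 (10 µM), PGD2 (10 µM) or vehicle for 48 h.

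All values below are deposited log2 values, with n = 3 libraries per group, group values as mean ± SD and differences with their SE. The depth per library is unknown, since the tables hold no counts. An exact 0 in the sorted-cell tables need not mean absence, as Gapdh, present in every cell, was listed at 0 in 2 of the 3 intestinal tuft libraries. How often this holds is unknown, and a gene with such a 0 is therefore given library by library. Libraries of one group correlated across genes at r = 0.724 to 0.845 in the KC pancreas, 0.817 to 0.879 in the intestine, 0.967 to 0.98 in BMM and 0.989 to 0.993 in mPSC. Genes are not independent replicates of each other.

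Tuft cells of the KC pancreas were first compared with the other sorted pancreatic epithelial cells, to see what sets them apart and which eicosanoid enzymes they express. Most tuft cell markers were higher, and most acinar markers and some islet hormone genes lower. Matk, a tyrosine kinase, stood at 7.57 ± 0.44 in tuft and 1.22 ± 0.83 in non-tuft cells, a rise of 6.35 (SE 0.52, adjusted p = 0.0014). Trpm5, the cation channel of taste signalling, was listed at 1.00, 0 and 0 in the non-tuft libraries and at 6.72, 6.26 and 6.73 in the tuft libraries (adjusted p = 0.0014). The pancreatic polypeptide gene Ppy fell by 10.04 (SE 0.79, adjusted p = 0.00134), from 11.22 ± 1.51 to 1.18 ± 1.15, and somatostatin, Sst, fell by 7.78 (SE 0.57, adjusted p = 0.00117), from 9.60 ± 1.17 to 1.82 ± 0.45.

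Of 28 tuft cell markers tested in the pancreas, 22 rose (26 adjusted over the list alone; camera adjusted p = 2.01e-34, or 0.107 with an estimated correlation). Among the largest rises were Rac2, a GTPase of blood cells, listed at 0, 0 and 2.80 in the non-tuft libraries and at 8.56, 8.22 and 8.82 in the tuft libraries, and the Src-family kinase gene Hck, listed at 2.20, 0 and 3.17 in the non-tuft libraries and at 8.88, 9.35 and 9.24 in the tuft libraries (adjusted p = 0.00249 for both). Folr1, Ly6g6f and the sort gene Siglecf were listed at 0 in the 3 non-tuft libraries, so no fold is given. In the tuft libraries Folr1 stood at 7.26 ± 0.27, Ly6g6f at 7.40 ± 0.28 and Siglecf at 6.68 ± 0.29. Taste transduction genes rose in 1 of 5 members tested, Trpm5 (2 adjusted over the list alone; camera adjusted p = 0.00214, or 0.198 with an estimated correlation). Gnat3, the taste G protein gustducin, did not pass (adjusted p = 0.504). It was listed at 6.82, 1.56 and 3.54 in the non-tuft and at 5.22, 5.64 and 6.89 in the tuft libraries.

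One KC non-tuft library carried tuft transcripts. The 28 tuft markers averaged 2.96 in non-tuft replicate 1, against 0.73 and 1.1 in the other non-tuft libraries, and the 16 acinar markers in the table averaged 6.73 there against 11 and 11.2. Rgs13, a regulator of G protein signalling, stood at 7.74, 0.49 and 0.59 in the 3 non-tuft and at 10.91, 11.01 and 10.03 in the 3 tuft libraries. Its rise passed at adjusted p = 0.0471 but not without tuft replicate 1, 2 or 3 (0.179, 0.154 and 0.163) or non-tuft replicate 2 or 3 (0.139 and 0.142).

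The enzymes that make prostaglandin D2 and cysteinyl leukotrienes were higher in KC tuft cells. Of 13 prostanoid and leukotriene synthesis genes tested, 7 rose and none fell (7 adjusted over the list alone; camera adjusted p = 1.72e-05, or 0.191 with an estimated correlation). Hpgds, the hematopoietic prostaglandin D synthase, was listed at 3.96, 0 and 0 in the non-tuft libraries and at 6.71, 6.65 and 6.27 in the tuft libraries (adjusted p = 0.0298). Cyclooxygenase 1, Ptgs1, was listed at 1.48, 0 and 0.46 in the non-tuft libraries and at 5.55, 4.98 and 5.26 in the tuft libraries (adjusted p = 0.00908). The 5-lipoxygenase gene Alox5 was listed at 4.24, 0 and 3.15 in the non-tuft libraries and at 8.42, 9.40 and 9.09 in the tuft libraries (adjusted p = 0.011). Its activating protein gene, Alox5ap, rose by 5.34 (SE 0.69, adjusted p = 0.00777) from 3.14 ± 1.58 to 8.48 ± 0.26, and Ltc4s, which forms cysteinyl leukotrienes, rose by 4.88 (SE 0.75, adjusted p = 0.0139). Pla2g4a, the phospholipase that releases arachidonic acid, rose by 2.21 (SE 0.44, adjusted p = 0.0345), and Hpgd, which inactivates prostaglandins, by 4.07 (SE 0.53, adjusted p = 0.00777). Differences of -0.56 (SE 0.75) for the prostaglandin E synthase Ptges2, -0.36 (SE 0.30) for Ptges3 and -0.28 (SE 0.33) for the leukotriene A hydrolase Lta4h did not pass.

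Each of these 7 calls ended when some tuft library was left out. Without tuft replicate 1 all 7 were lost, the highest adjusted p being 0.141 for Hpgds. Without tuft replicate 2, 5 were lost (0.125 for Hpgds) and without tuft replicate 3, 6 (0.179 for Pla2g4a). Pla2g4a and Hpgds were also lost without non-tuft replicate 2 (0.11 and 0.0886) or non-tuft replicate 3 (0.101 and 0.084).

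Acinar markers and some islet markers were lower in KC tuft cells. Of 14 acinar markers tested 12 fell (14 adjusted over the list alone; camera adjusted p = 7.34e-18, or 0.191 with an estimated correlation). The elastase gene Cela2a fell by 5.86 (SE 0.91, adjusted p = 0.0144), chymotrypsinogen Ctrb1 by 6.19 (SE 0.82, adjusted p = 0.00827) and the lipase gene Cel by 6.06 (SE 0.95, adjusted p = 0.0144). All 3 were lost without tuft replicate 1 (0.0699, 0.0551 and 0.0762), tuft replicate 2 (0.0748, 0.0507 and 0.0696) or tuft replicate 3 (0.086, 0.0515 and 0.0668), and Cel also without non-tuft replicate 2 (0.0508). Sycn was lost without 5 of the 6 libraries. Colipase, Clps, fell by 7.12 (SE 0.72, adjusted p = 0.0029). Cela3a, an elastase gene, and Erp27, a chaperone of the acinar endoplasmic reticulum, were listed at 0 in the 3 tuft libraries and at 3.31, 9.91 and 9.89 and 5.09, 8.93 and 8.46 in the non-tuft libraries. The call of Cela3a was lost without tuft replicate 1, 2 or 3 (0.14, 0.124 and 0.153). Of 12 enteroendocrine and islet markers 1 rose and 4 fell (1 and 9 adjusted over the list alone; camera adjusted p = 1.71e-07, or 0.107 with an estimated correlation). The rise, of Sct, was lost without tuft replicate 1, 2 or 3 (0.165, 0.144 and 0.194) or non-tuft replicate 2 or 3 (0.0969 and 0.0613), and the fall of Pyy without tuft replicate 1 (0.0551). The list averaged 4.47 in tuft replicate 2, against 0.66 and 2.24 in the other tuft libraries.

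Gastric metaplasia genes, active in stomach and in injured pancreas, rose in 1 and fell in 1 of 12 members (4 and 1 adjusted over the list alone; camera adjusted p = 0.00098, or 0.34 with an estimated correlation). Tff1, a stomach trefoil peptide, stood at 12.13 ± 2.14 in tuft and 8.01 ± 0.26 in non-tuft cells (adjusted p = 0.046), with 14.38 in tuft replicate 1. Its call was lost without tuft replicate 1 or 3 (0.0699 and 0.165) or non-tuft replicate 1, 2 or 3 (0.0616, 0.123 and 0.142). The gastric mucin Muc6 fell by 1.97 (SE 0.38, adjusted p = 0.0304), a call lost without tuft replicate 1, 2 or 3 (0.107, 0.13 and 0.117) or non-tuft replicate 2 (0.0974). The gastrokine Gkn1, at 13.09, 6.98 and 9.80 in the tuft and 5.41, 6.43 and 5.98 in the non-tuft libraries, did not pass (adjusted p = 0.145). Among 11 ductal markers 1 rose, the keratin Krt8 (3 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0147, or 0.361 with an estimated correlation). Krt8 rose by 2.94 (SE 0.46, adjusted p = 0.0148), and was lost without tuft replicate 1, 2 or 3 (0.0698, 0.0812 and 0.0961) or non-tuft replicate 2 or 3 (0.0683 and 0.0676). Dissociation and immediate early genes passed as a set, lower in tuft cells, with 0 of 13 members past limma's gene-wise test (camera adjusted p = 0.000217, or 0.341 with an estimated correlation). No member of the immune (6 tested), eosinophil and mast cell (3), goblet (6), Paneth (1), intestinal stem cell (5), proliferation (5) or prostanoid receptor (1) lists passed in limma. Of 7 enterocyte markers 1 rose, Fabp1, listed at 0 in the 3 non-tuft and at 5.29, 6.80 and 5.35 in the tuft libraries. Of 2 mesenchymal markers 1 fell, Sparc, listed at 4.91, 4.20 and 5.47 in non-tuft and at 0, 0.41 and 0 in tuft libraries. Its call was lost without tuft replicate 1 or 3 (0.0575 and 0.0534), and it was not tested without any one non-tuft library. The mesenchymal list averaged 6.82 in non-tuft replicate 3, against 3.11 and 2.8 in the other non-tuft libraries.

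In all, 297 of 10112 genes passed in the pancreas, 184 higher and 113 lower in tuft cells, while 1506 genes had an unadjusted p under 0.05. With 3 libraries per group, simulated changes of 4-fold were called in 14.9% and of 16-fold in 74.2% of genes, so smaller differences were largely out of reach. The count was 31, 58 and 30 without tuft replicate 1, 2 and 3, 113 and 117 without non-tuft replicate 2 and 3, and 412 without non-tuft replicate 1. Part of each drop lies in the filter, since 64 of the 184 higher genes were not tested without any one tuft library and 49 of the 113 lower genes without any one non-tuft library. It was 182 with the replicate block and 59 at adjusted p under 0.01.

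Wild-type intestinal tuft cells were compared with other intestinal epithelial cells in the same way. All 32 tuft markers tested rose (32 adjusted over the list alone; camera adjusted p = 1.01e-31, or 0.0438 with an estimated correlation). Hck rose by 11.52 (SE 0.25, adjusted p = 6.45e-07), from 0.70 ± 0.22 to 12.22 ± 0.21, and Rac2 by 10.53 (SE 0.30, adjusted p = 2.02e-06), from 0.55 ± 0.33 to 11.08 ± 0.31. Rgs13 stood at 10.46 ± 0.07 against 0.40 ± 0.34. Taste transduction genes rose in 5 of 7 (5 adjusted over the list alone; camera adjusted p = 0.00265, or 0.0908 with an estimated correlation), among them Plcb2, the phospholipase of taste signalling, listed at 0, 0 and 1.92 in the non-tuft libraries and at 4.76, 5.42 and 5.02 in the tuft libraries (adjusted p = 0.00314). Gnat3 was listed at 0 in the 3 non-tuft and at 4.92, 5.22 and 5.31 in the tuft libraries.

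Eicosanoid enzymes were raised in intestinal tuft cells as well. Of 11 synthesis genes 6 rose and none fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.00184, or 0.0908 with an estimated correlation). Alox5 was listed at 0.14, 0.63 and 0.14 in the non-tuft and at 9.64, 9.89 and 9.73 in the tuft libraries (adjusted p = 2.92e-06). Ptgs1 was listed at 0.09, 0 and 0 in the non-tuft and at 7.75, 7.87 and 7.11 in the tuft libraries (adjusted p = 4e-05). Hpgds was listed at 1.44, 0 and 4.02 in the non-tuft and at 7.35, 7.63 and 7.90 in the tuft libraries (adjusted p = 0.00351). Ltc4s rose by 5.63 (SE 0.50, adjusted p = 0.000398), from 1.90 ± 0.96 to 7.53 ± 0.14. Pla2g4a was listed at 0, 0 and 2.56 in the non-tuft libraries and at 7.01, 6.93 and 6.78 in the tuft libraries (adjusted p = 0.00123). Hpgd stood at 6.76 ± 0.37 in tuft and 6.91 ± 0.20 in non-tuft cells, a difference of -0.15 (SE 0.27) that did not pass.

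**Figure D1:**
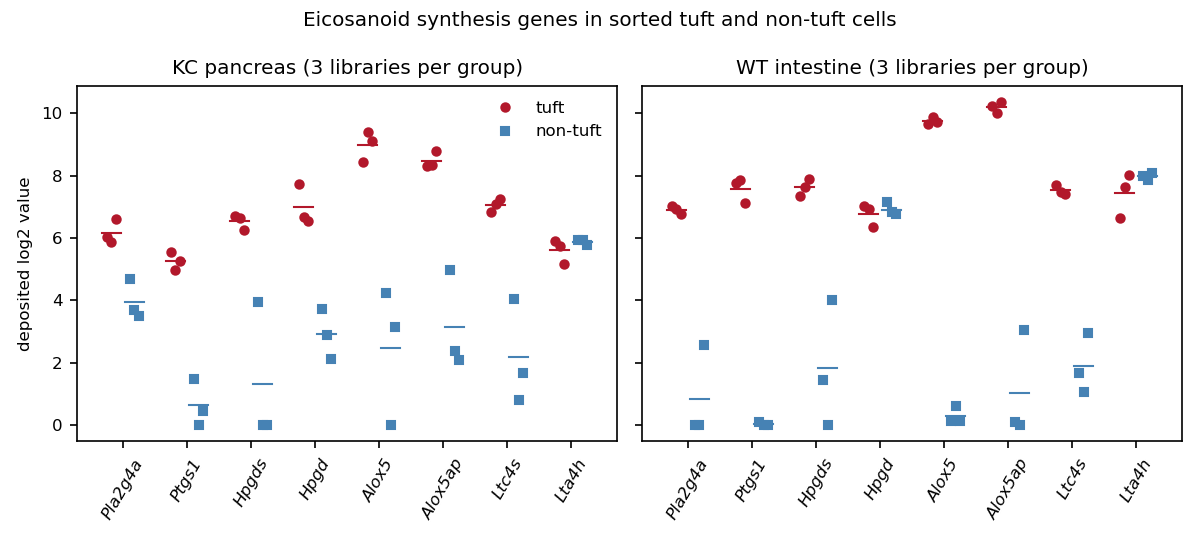
Deposited log2 value (y axis) of 8 eicosanoid synthesis genes (x axis) in KC pancreas (left) and wild-type intestine (right), where each point is 1 library, red circles are tuft and blue squares non-tuft cells, and short lines are means of 3 libraries. Alox5 lies at 8.42 to 9.40 in the KC tuft libraries and at 0 to 4.24 in the KC non-tuft libraries, and Hpgds at 6.27 to 6.71 against 0 to 3.96.

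Enterocyte markers were lower in intestinal tuft cells, as were some goblet and proliferation genes. Of 15 enterocyte markers 12 fell (1 higher and 13 lower adjusted over the list alone; camera adjusted p = 7.1e-08, or 0.182 with an estimated correlation). Intestinal alkaline phosphatase, Alpi, fell by 4.29 (SE 0.50, adjusted p = 0.00119), from 9.78 ± 0.66 to 5.49 ± 0.91, and the apolipoprotein Apob by 2.71 (SE 0.26, adjusted p = 0.000541). Goblet cell markers fell in 4 of 9 (4 adjusted over the list alone; camera adjusted p = 0.0122, or 0.41 with an estimated correlation), with a list mean of 8.37 in non-tuft replicate 2 against 3.92 and 5.33 in the other non-tuft libraries. The mucin Muc2 and the trefoil peptide Tff3 were among these 4, but not without tuft replicate 2 (0.0696 and 0.096) or tuft replicate 3 (0.0658 and 0.0811), nor Tff3 without non-tuft replicate 3 (0.0762). The goblet gene Agr2 was lost without tuft replicate 2 (0.0548). Paneth cell markers passed in 0 of 5 by limma, with a list mean of 10.5 in non-tuft replicate 1 against 1.91 and 2.6. Proliferation genes fell in 3 of 10 (6 adjusted over the list alone; camera adjusted p = 0.00393, or 0.0908 with an estimated correlation), the helicase gene Mcm5 only while all of tuft replicates 1 and 2 and non-tuft replicates 1 and 2 were kept (0.0792, 0.0898, 0.0856 and 0.0807 without each). Dissociation and immediate early genes fell in 4 of 12 (4 adjusted over the list alone; camera adjusted p = 0.0121, or 0.248 with an estimated correlation). One of these, Fos, was lost without non-tuft replicate 1, 2 or 3 (0.0842, 0.0672 and 0.0957), while the phosphatase Dusp1 fell by 3.49 (SE 0.55, adjusted p = 0.00384).

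Some ductal markers also differed. Among 9 ductal markers in the intestine 4 rose and 2 fell, with Krt18 up by 6.58 (SE 0.22, adjusted p = 2.92e-06), from 7.49 ± 0.27 to 14.07 ± 0.19, and the progenitor factor Sox9 up by 4.36 (SE 0.44, adjusted p = 0.000634). The sort gene Ptprc, which encodes the leukocyte antigen Cd45 used as a label in the sort, was listed at 0 in the 3 non-tuft libraries and at 8.82, 8.12 and 8.32 in the tuft libraries, and was the 1 of 3 immune markers past the test. The 1 eosinophil and mast cell marker tested rose, Kit, listed at 0, 0 and 2.55 in the non-tuft libraries and at 5.01, 3.82 and 4.61 in the tuft libraries, a call lost without tuft replicate 1 or 3 (0.0542 and 0.0522). Of 4 enteroendocrine markers Chga fell, lost without tuft replicate 1, 2 or 3 (0.115, 0.132 and 0.129), and of 6 stem cell markers Olfm4, lost without non-tuft replicate 1 or 3 (0.0511 and 0.0571). Of the gastric genes 2 of 6 rose and 1 fell. The endothelial receptor gene Tek was listed at 0 in the 6 non-tuft libraries of both tissues, and stood at 5.49 ± 1.24 in the pancreatic and 5.16 ± 0.71 in the intestinal tuft libraries. Outside the lists, the prolactin receptor Prlr fell by 6.19 (SE 0.40, adjusted p = 7.5e-05), from 7.06 ± 0.06 to 0.87 ± 0.40. In the intestine 1960 of 9359 genes passed, 992 higher and 968 lower. The count was 1272, 1113 and 1237 without tuft replicate 1, 2 and 3, 1274 and 1191 without non-tuft replicate 1 and 3, and 948 at adjusted p under 0.01. The filter left 291 of the higher genes untested without any one tuft library and 202 of the lower genes without any one non-tuft library.

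Next, the tuft effects of both tissues were set against each other by testing their difference. Tissue, Kras genotype and age changed together, so the difference is not one of tissue alone. Each effect is also relative to the non-tuft cells of its own tissue, so a difference can lie in the tuft or the non-tuft cells. The tuft effect was lower in the KC pancreas for 7 of 28 tuft markers (12 adjusted over the list alone; camera adjusted p = 2.26e-10, or 0.15 with an estimated correlation). Without KC non-tuft replicate 1, the library with tuft transcripts, 7 of 28 passed as well, with a median difference of -1.76 in place of -2.27. For eicosanoid genes the effect was lower for Pla2g4a (adjusted p = 0.0217) and Ptgs1 (adjusted p = 0.0295), and higher by 4.22 for Hpgd (SE 0.61, adjusted p = 0.00229). For the first 2 the size is left open, given the zeros in non-tuft libraries listed above. That of Hpgds, with zeros in non-tuft libraries of both tissues, did not pass (adjusted p = 0.885), which neither shows nor excludes a difference of several fold. Somatostatin, Sst, had one of the largest differences (-7.10, SE 0.91, adjusted p = 0.00134). The keratin Krt23 was listed at 1.98, 0 and 2.34 in the WT intestine non-tuft libraries and at 9.70, 9.86 and 9.81 in the WT intestine tuft libraries, but at 6.73 ± 0.17 in pancreatic non-tuft and 5.78 ± 0.88 in pancreatic tuft cells (adjusted p = 4.76e-05).

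The difference was negative for 9 of 11 acinar markers (10 adjusted over the list alone; camera adjusted p = 1.2e-10, or 0.15 with an estimated correlation). It was positive for 2 of 7 enterocyte markers (5 adjusted over the list alone; camera adjusted p = 6.5e-05, or 0.0751 with an estimated correlation) and for 1 of 6 goblet markers (4 adjusted over the list alone; camera adjusted p = 0.0106, or 0.15 with an estimated correlation). That marker, Spink4, was lost without any of 9 of the 12 libraries (0.0672 to 0.111), all but pancreatic tuft replicate 3, pancreatic non-tuft replicate 2 and intestinal non-tuft replicate 3. Proliferation genes passed as a set, in the positive direction, with 0 of 5 members past limma's gene-wise test (3 adjusted over the list alone; camera adjusted p = 0.0237, or 0.171 with an estimated correlation). Of 8318 genes tested in both tissues 448 differed, 233 with a higher and 215 with a lower effect in the pancreas. The count was 272 and 254 without pancreatic tuft replicate 1 and 2, 200, 234 and 275 without intestinal tuft replicate 1, 2 and 3, 288 and 267 without intestinal non-tuft replicate 1 and 3, and 120 at adjusted p under 0.01. Of the 448, 9 to 66 were not tested once a library was left out. Pla2g4a ended at up to 0.0618 (intestinal tuft replicate 1) and was also lost without intestinal tuft replicate 2, intestinal non-tuft replicate 1 or pancreatic tuft replicate 1 or 2. Ptgs1 ended at up to 0.0811 (pancreatic tuft replicate 2) and was also lost without pancreatic tuft replicate 1 or 3 or intestinal non-tuft replicate 1 or 3.

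Genes higher in tuft cells were shared between the tissues. Among 8319 entries tested in both tables (the 8318 genes and a second entry of a repeated symbol), 119 passed as higher in tuft cells in pancreas and intestine, where 17.2 would be shared by independent lists, and 10 passed as lower in both (3.06 for independent lists). Another 4 were called in opposite directions. This overlap was chosen after the values were seen.

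PGD2 given to resting BMM tested the direct response of macrophages to the prostaglandin made by Hpgds. Genes of antioxidant defence and glutathione synthesis rose, and genes of the cell cycle fell. Hmox1, the heme oxygenase, rose by 4.23 (SE 0.23, adjusted p = 9.91e-07), from 8.12 ± 0.50 to 12.35 ± 0.18. Gclm, a subunit of the enzyme limiting glutathione synthesis, rose by 4.37 (SE 0.28, adjusted p = 1.95e-06), and the quinone reductase Nqo1 by 3.52 (SE 0.16, adjusted p = 2.83e-07). Survivin, Birc5, fell by 1.80 (SE 0.07, adjusted p = 2.33e-07), from 5.35 ± 0.08 to 3.55 ± 0.04, and cyclin B2, Ccnb2, by 1.84 (SE 0.11, adjusted p = 1.17e-06).

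Of 19 targets of NRF2, the transcription factor of the antioxidant response, 17 rose (17 adjusted over the list alone; camera adjusted p = 1.64e-15, or 0.031 with an estimated correlation). All 16 proliferation genes fell (16 adjusted over the list alone; camera adjusted p = 2.22e-14, or 0.002 with an estimated correlation). Cholesterol biosynthesis genes rose in 14 of 17 (14 adjusted over the list alone; camera adjusted p = 4.18e-06, or 0.447 with an estimated correlation), among them the low density lipoprotein receptor Ldlr by 1.92 (SE 0.30, adjusted p = 0.000633) and Hmgcr, the rate-limiting enzyme of the pathway, by 1.01 (SE 0.14, adjusted p = 0.00033). PPAR targets rose in 7 and fell in 2 of 14 (8 and 3 adjusted over the list alone; camera adjusted p = 0.0451, or 0.522 with an estimated correlation), with the lipid droplet gene Plin2 up by 1.91 (SE 0.13, adjusted p = 3.38e-06). With the replicate block this set test did not pass (adjusted p = 0.128). Interferon-stimulated genes fell in 9 of 24 (10 adjusted over the list alone; camera adjusted p = 0.000119, or 0.558 with an estimated correlation), such as Oasl2 by 1.98 (SE 0.35, adjusted p = 0.00145).

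Prostanoid genes responded. Of 4 receptor genes 3 rose and 1 fell, and no PGD2 receptor gene was listed for BMM or mPSC. Ptger2, a PGE2 receptor, rose by 2.64 (SE 0.19, adjusted p = 3.4e-06), from 0.84 ± 0.23 to 3.48 ± 0.31, and the prostacyclin receptor Ptgir by 2.23 (SE 0.15, adjusted p = 3.06e-06), while Ptger4, another PGE2 receptor, fell by 1.27 (SE 0.19, adjusted p = 0.000527). The rise of Ptger1 (0.40, adjusted p = 0.0263) was lost without PGD2 replicate 1 or 3 (0.0523 and 0.0947) or vehicle replicate 1 or 2 (0.0989 and 0.0845). Synthesis genes rose in 7 and fell in 1 of 13 (7 and 1 adjusted over the list alone; camera adjusted p = 0.025, or 0.286 with an estimated correlation). Ptges, the inducible prostaglandin E synthase, rose by 1.65 (SE 0.16, adjusted p = 2.52e-05), and the prostaglandin exporter Abcc4 by 1.61 (SE 0.24, adjusted p = 0.000556). Hpgds fell by 0.82 (SE 0.16, adjusted p = 0.00219). The rise of Ptgs1 (adjusted p = 0.0347) was lost without PGD2 replicate 1 or 3 (0.129 and 0.0615) or vehicle replicate 2 or 3 (0.113 and 0.0699), and that of Ptgs2 (adjusted p = 0.0177) without PGD2 replicate 1 or 2 (0.0658 and 0.066) or vehicle replicate 1 or 3 (0.0507 and 0.0597). With the replicate block Tbxas1 (0.38) and Ptges3 (0.18) passed too (adjusted p = 0.0387 and 0.0377).

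Ccl7, Ccl12 and Ccl2, ligands that attract monocytes, fell in resting BMM by 3.65 (SE 0.57, adjusted p = 0.000726), 2.63 (SE 0.42, adjusted p = 0.000816) and 2.56 (SE 0.46, adjusted p = 0.00162). On the rising side, the C-type lectin Clec4n rose by 5.04 (SE 0.34, adjusted p = 2.98e-06), from 4.28 ± 0.82 to 9.31 ± 0.20, and the iron exporter Slc40a1 by 3.91 (SE 0.35, adjusted p = 1.56e-05). The glutathione transferase Gsta3 was listed at 0.21, 0.10 and 0 in vehicle and at 5.93, 5.82 and 5.98 in PGD2 libraries (adjusted p = 7.11e-08). Mgst2, a microsomal member of that enzyme class, was listed at 0 in the 3 vehicle libraries and at 6.16, 5.65 and 5.24 with PGD2. Classical activation genes rose in 2 and fell in 4 of 22, and alternative activation genes rose in 1 of 10, arginase 1 (Arg1), by 2.59 (SE 0.60, adjusted p = 0.00705). The lectin Clec10a differed by 1.75 and passed with the replicate block (adjusted p = 0.000302) but not without it (0.201). Heat shock genes rose in 2 of 9, cAMP and CREB targets rose in 1 and fell in 1 of 7, and macrophage identity genes rose in 2 and fell in 4 of 10. A neutrophil gene, S100a8, rose by 3.46 (SE 0.47, adjusted p = 0.000299), with 2 members of that list tested. Mesenchymal markers rose in 1 and fell in 1 of 3. The cAMP target that rose, Per1, was lost without 4 of the 6 libraries (0.0574 to 0.125), and the mesenchymal fall, of Vim, without 5 (0.0528 to 0.102). So were the identity genes Cd68 without 5 (0.0544 to 0.0837) and Fcgr1 without 3 (0.0815 to 0.0946), and the classical activation gene Tnf without 3 (0.0534 to 0.0604). Blocked by replicate, classical activation genes rose in 4 and fell in 5, alternative activation genes in 2 and 1, cAMP targets in 1 and 2, and PPAR targets in 8 and 4. In all, 2901 of 8915 genes passed (1448 higher, 1453 lower), and 4179 with the block. Of the 2901, 698 changed by at least 2-fold and 1892 passed at adjusted p under 0.01.

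**Figure D2:**
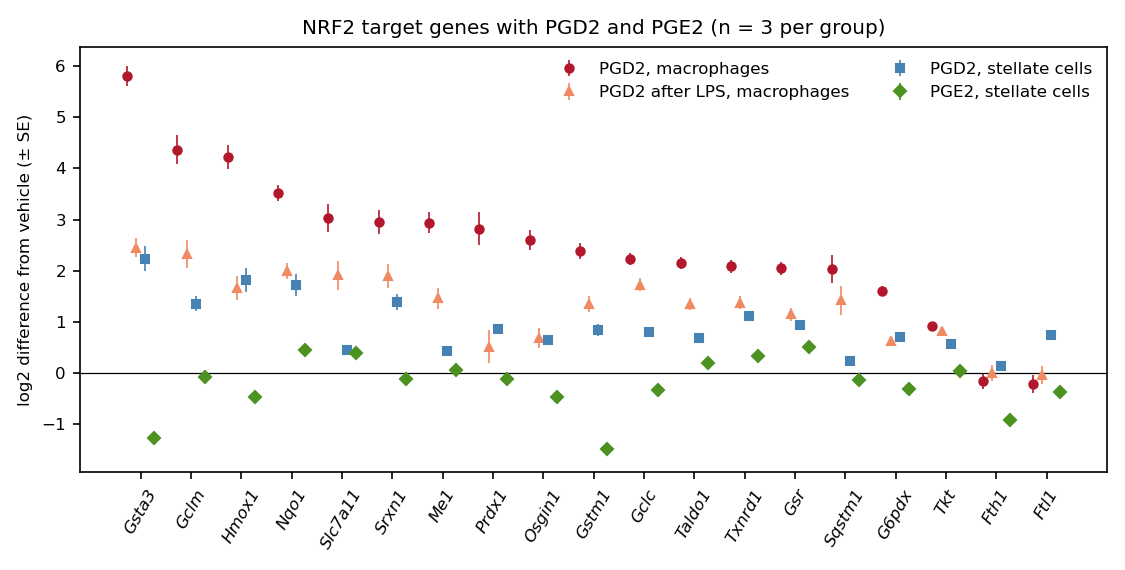
Log2 difference from vehicle (y axis, ± SE, understated in mPSC, n = 3 libraries per group) of the NRF2 targets (x axis). PGD2 is shown in resting BMM (red circles), BMM after LPS (orange triangles) and mPSC (blue squares), and PGE2 in mPSC (green diamonds). Gsta3 lies at 5.80, 2.45 and 2.24 with PGD2 in these 3 settings and at -1.27 with PGE2.

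LPS alone, the background of the next comparison, raised inflammatory genes in vehicle-treated BMM. The chemokine Ccl5 rose by 11.65 (SE 0.28, adjusted p = 1.91e-10), from 1.05 ± 0.19 to 12.70 ± 0.51, and complement factor B, Cfb, by 9.57 (SE 0.07, adjusted p = 4.49e-14). All 24 interferon-stimulated genes rose (24 adjusted over the list alone; camera adjusted p = 2.03e-14, or 0.239 with an estimated correlation), as did 20 of 22 classical activation genes (20 adjusted over the list alone; camera adjusted p = 7.11e-11, or 0.126 with an estimated correlation). All 16 proliferation genes fell (16 adjusted over the list alone; camera adjusted p = 2.3e-12, or 0.00345 with an estimated correlation). Outside that list, cyclin A2, Ccna2, fell by 6.37 (SE 0.11, adjusted p = 1.69e-11), from 6.83 ± 0.09 to 0.46 ± 0.05. NRF2 targets rose in 15 and fell in 2 of 19 (15 and 2 adjusted over the list alone; camera adjusted p = 0.000952, or 0.395 with an estimated correlation). Prostanoid synthesis genes rose in 4 and fell in 6 of 13. Ptges rose by 7.71 (SE 0.16, adjusted p = 6.74e-11) and Ptgs2, cyclooxygenase 2, by 5.82 (SE 0.53, adjusted p = 4.18e-06), while Hpgds fell by 2.06 (SE 0.16, adjusted p = 9.42e-07) and Alox5 by 2.55 (SE 0.29, adjusted p = 1.98e-05). Of 4 receptor genes 3 rose, Ptger2 by 2.05 (SE 0.19, adjusted p = 3.87e-06) and Ptgir by 2.22 (SE 0.15, adjusted p = 5.03e-07) among them. Passing only with the replicate block were Ptger4 (0.41, adjusted p = 0.0451), Tbxas1 (0.49, 0.0074) and Pla2g4a (-0.33, 0.0418), which gave 4 and 0 receptors and 5 and 7 synthesis genes higher and lower. The fall of Ptgs1 was lost without 4 of the 6 libraries (0.0707 to 0.0986) and the rise of Abcc4 without 3 (0.0872 to 0.151).

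For the remaining lists with LPS, counts of members higher and lower were 4 and 4 for alternative activation, 2 and 2 for cAMP targets, 5 and 5 for PPAR targets, 3 and 5 for heat shock, 1 and 8 for cholesterol biosynthesis, 5 and 2 for macrophage identity, 2 and 0 for neutrophil markers and 2 and 1 for mesenchymal markers. Blocked counts were 2 and 8 for cholesterol biosynthesis, 6 and 3 for macrophage identity, 5 and 6 for PPAR targets, 4 and 5 for alternative activation and 2 and 3 for cAMP targets. Of the mesenchymal calls, Vim was lost without vehicle replicate 2 (0.0528) and Acta2 without LPS vehicle replicate 1, 2 or 3 (0.0794, 0.0632 and 0.0517) or vehicle replicate 1 (0.0531). Of 8915 genes 5661 passed (6565 with the block), 2573 higher and 3088 lower, and 2058 by at least 2-fold.

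In BMM already exposed to LPS, PGD2 lowered interferon-stimulated genes and raised NRF2 targets and heat shock genes. Cxcl10, an interferon-induced chemokine, fell by 3.72 (SE 0.58, adjusted p = 0.00161), from 8.71 ± 0.36 to 4.99 ± 0.63. Mx1, an antiviral GTPase, fell by 2.72 (SE 0.40, adjusted p = 0.00112), and Stat1, the transducer of interferon signals, by 1.46 (SE 0.12, adjusted p = 4.62e-05). Nqo1 rose by 1.99 (SE 0.16, adjusted p = 3.66e-05), the glutathione synthesis gene Gclc by 1.72 (SE 0.13, adjusted p = 2.95e-05) and the chaperone Hspa8 by 1.55 (SE 0.13, adjusted p = 5.39e-05).

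Of 24 interferon-stimulated genes 17 fell (20 adjusted over the list alone; camera adjusted p = 2.6e-11, or 0.243 with an estimated correlation). NRF2 targets rose in 16 of 19 (16 adjusted over the list alone; camera adjusted p = 7.49e-12, or 0.127 with an estimated correlation), and heat shock genes in 8 of 9 (9 adjusted over the list alone; camera adjusted p = 1.46e-06, or 0.197 with an estimated correlation). Macrophage identity genes fell in 3 of 10 (1 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.022, or 0.243 with an estimated correlation), the Fc receptor Fcgr1 by 1.95 (SE 0.36, adjusted p = 0.00357). The other members were Mertk, lost without LPS PGD2 replicate 2 or 3 (0.0739 and 0.0587) or LPS vehicle replicate 1 or 3 (0.0601 and 0.0623), and Cx3cr1, lost without LPS PGD2 replicate 2 or 3 (0.0993 and 0.0957) or LPS vehicle replicate 1 (0.0887). In the fit with the replicate block 1 identity gene rose and 6 fell.

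Inflammatory genes went in both directions after LPS. Nos2, the inducible nitric oxide synthase, fell by 1.93 (SE 0.31, adjusted p = 0.00195), from 8.68 ± 0.86 to 6.75 ± 0.09, and Ccl5 by 1.32 (SE 0.28, adjusted p = 0.00765), whereas the neutrophil chemokines Cxcl1 and Cxcl5 rose by 1.99 (SE 0.42, adjusted p = 0.00645) and 2.54 (SE 0.33, adjusted p = 0.000519). Classical activation genes rose in 4 and fell in 3 of 22. The largest rise was Uchl1, a ubiquitin hydrolase, by 3.23 (SE 0.19, adjusted p = 6.71e-06), and Ccl12 fell by 3.77 (SE 0.42, adjusted p = 0.00024). Prostanoid synthesis genes rose in 4 and fell in 1 of 13. Pla2g4a rose by 1.32 (SE 0.17, adjusted p = 0.000592) and Ptges fell by 0.96 (SE 0.16, adjusted p = 0.00205), while Hpgds differed by 0.24 (SE 0.16) and did not pass. Ptgs2 rose by 2.17 (SE 0.53, adjusted p = 0.0147), a call lost without LPS PGD2 replicate 2 (0.0516). Abcc4 rose by 0.81 (SE 0.24, adjusted p = 0.0343), lost without LPS PGD2 replicate 1 or 3 (0.115 and 0.0743) or LPS vehicle replicate 2 or 3 (0.105 and 0.121). Of the 4 receptors Ptger2 rose, by 0.83 (SE 0.19, adjusted p = 0.00944). PPAR targets rose in 7 and fell in 1 of 14, and neutrophil markers rose in 1 and fell in 1 of 2. One member each fell among proliferation, alternative activation, cAMP, cholesterol and mesenchymal genes. Of these, the cAMP target Rgs2 was lost without LPS PGD2 replicate 1 or 3 (0.117 and 0.0652) or LPS vehicle replicate 1 or 2 (0.0651 and 0.11), and the cholesterol gene Dhcr7 without LPS PGD2 replicate 1 or 2 (0.0673 and 0.112) or LPS vehicle replicate 1 or 3 (0.0836 and 0.0841). Adjusted over the list alone, no cAMP or cholesterol gene passed in limma. The neutrophil fall, of Camp, was lost without LPS vehicle replicate 1 (0.0653). Passing only with the block were Ptger4 (-0.57, adjusted p = 0.0213), Tbxas1 (-0.47, 0.0194) and Alox5ap (0.43, 0.0482). Counts higher and lower with the replicate block were 5 and 2 for synthesis genes, 1 and 1 for receptors, 6 and 3 for classical activation, 7 and 3 for PPAR targets, 0 and 2 for proliferation genes, 1 and 2 for alternative activation and 1 and 1 for cholesterol genes. Arg1 differed by -1.51, which passed with the replicate block (adjusted p = 0.0356) and not without it (0.0931). Of 8915 genes 2166 passed (1213 higher, 953 lower), 394 by at least 2-fold and 1104 at adjusted p under 0.01. With the replicate block 3604 passed (2009 higher, 1595 lower), against 4179 without LPS.

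Whether PGD2 acted differently with and without LPS was tested as the difference of its effects. The effect on proliferation genes was higher after LPS for 15 of 16 (15 adjusted over the list alone; camera adjusted p = 6.16e-12, or 0.00358 with an estimated correlation), although these genes then started at a median of 0.912, against 5.72 in resting cells. It was lower after LPS for 13 of 19 NRF2 targets (15 adjusted over the list alone; camera adjusted p = 6.28e-08, or 0.177 with an estimated correlation) and for 6 of 17 cholesterol genes (8 adjusted over the list alone, 10 with the replicate block; camera adjusted p = 8.29e-05, or 0.478 with an estimated correlation), of which none rose and 1 fell with PGD2 after LPS in limma. For heat shock genes it was higher in 4 of 9 (4 adjusted over the list alone; camera adjusted p = 0.00599, or 0.478 with an estimated correlation), Dnajb1 being lost without any of 6 of the 12 libraries (0.0525 to 0.0701). The effect on Arg1 was lower by 4.10 (SE 0.85, adjusted p = 0.00571) and that on Clec4n by 3.64 (SE 0.48, adjusted p = 0.000538).

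**Figure D3:**
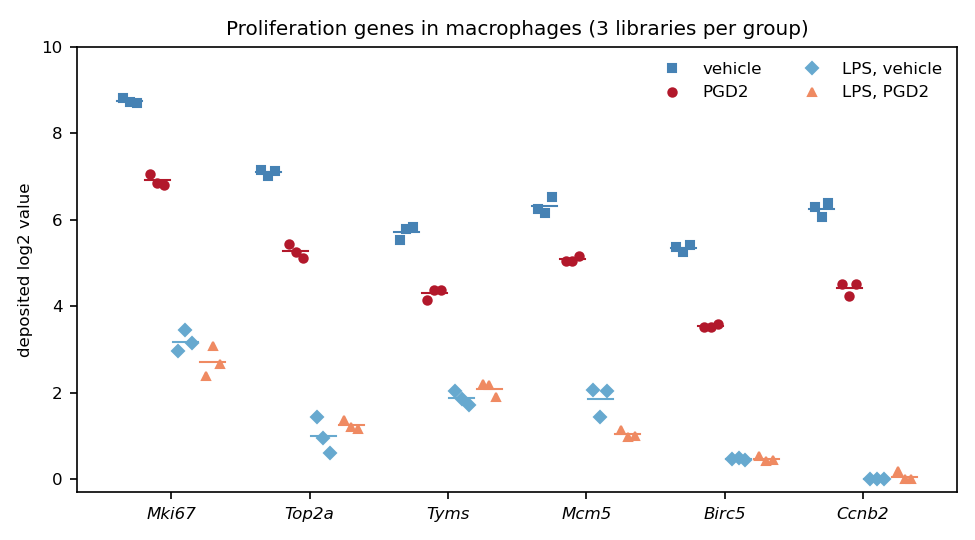
Deposited log2 value (y axis) of 6 proliferation genes (x axis) in BMM, where each point is 1 library, marks and colours give the 4 groups and short lines are means of 3 libraries. Birc5 stands at 5.35 ± 0.08 with vehicle and 3.55 ± 0.04 with PGD2, and all 6 genes are lower in both LPS groups than with vehicle alone.

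Among prostanoid genes the effect on Ptges was lower after LPS by 2.61 (SE 0.22), on Ptger2 by 1.82 (SE 0.26) and on Ptgir by 2.19 (SE 0.22), and on Hpgds it was higher by 1.07 (SE 0.22). Of 13 synthesis genes 2 effects were higher and 1 lower, but 2 and 6 with the replicate block, and of 4 receptors 0 and 2, but 1 and 3 with it. Lower only with the block were Alox5 (blocked adjusted p = 0.00452), Tbxas1 (0.00638), Abcc4 (0.0123), Alox5ap (0.0273), Ptgs1 (0.0494) and Ptger1 (0.0228), and higher only with it was Ptger4 (0.0367). For PPAR targets 2 effects were higher and 6 lower, for interferon-stimulated genes 2 and 6, for classical activation genes 4 and 2, for macrophage identity genes 1 and 2, and for alternative activation genes 0 and 2. With the block PPAR targets gave 4 and 7, interferon-stimulated genes 3 and 8, classical activation genes 6 and 3, identity genes 2 and 2, and alternative activation genes 0 and 3. Of the calls without it, Mx1 was lost without any of 6 of the 12 libraries (0.0549 to 0.0617), Ccl3 without 5 (0.0532 to 0.0585), and the cholesterol genes Ldlr without 2 (0.0523 and 0.0541) and Cyp51 without 1 (0.0514). In all 2301 of 8915 genes differed (1295 higher after LPS, 1006 lower), 701 by at least 2-fold and 1196 at adjusted p under 0.01, and 3689 with the replicate block. PGD2 moved 686 genes the same way in both states, 444 up (197 for independent lists) and 242 down (155), and 218 in opposite ways. With the replicate block 1303 moved the same way, 781 up (480 for independent lists) and 522 down (367), and 567 in opposite ways. At adjusted p under 0.01 these counts were 312 and 48.

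PGE2 in stellate cells asked how the neighbouring fibroblasts respond to the related prostaglandin. Myofibroblast genes were among those that rose. Smooth muscle actin, Acta2, rose by 1.63 (SE 0.15, blocked adjusted p = 0.00928), from 8.19 ± 0.19 to 9.82 ± 0.23, calponin, Cnn1, by 2.01 (SE 0.17, blocked adjusted p = 0.00876) and Serpine1, the inhibitor of plasminogen activators, by 2.59 (SE 0.17, blocked adjusted p = 0.00652). Clec3b and Cd34, genes of resting fibroblasts, fell by 3.50 (SE 0.27, blocked adjusted p = 0.00744) and 3.48 (SE 0.34, blocked adjusted p = 0.0107). In mPSC the words rose and fell refer to genes past the blocked test for a reason given below.

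Of 22 myofibroblast and matrix genes 13 rose and 1 fell with the block (14 and 4 without it, 15 and 4 adjusted over the list alone; camera adjusted p = 0.00905, or 0.651 with an estimated correlation). TGF-beta targets rose in 4 of 10 (6 without the block, 6 adjusted over the list alone; camera adjusted p = 0.018, or 0.651 with an estimated correlation), Ctgf by 1.34 (SE 0.15, blocked adjusted p = 0.0131). Cholesterol biosynthesis genes rose in 11 of 15 (14 without the block, 14 adjusted over the list alone; camera adjusted p = 0.000432, or 0.651 with an estimated correlation), Cyp51 by 0.77 (SE 0.11, blocked adjusted p = 0.0204). Prostanoid receptor genes fell in 4 of 5 (4 without the block, 5 adjusted over the list alone; camera adjusted p = 0.018, or 0.651 with an estimated correlation), Ptger4 by 1.22 (SE 0.08, blocked adjusted p = 0.00744), from 3.10 ± 0.14 to 1.88 ± 0.04. Among 11 synthesis genes 2 rose and 1 fell, Ptgs2 by 1.49 (SE 0.20, blocked adjusted p = 0.0163) and the prostaglandin importer Slco2a1 by 0.72 (SE 0.05, blocked adjusted p = 0.0114) on the rising side.

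The cAMP and CREB targets Nr4a1 and Nr4a3, early response receptors, rose by 2.09 (SE 0.12, blocked adjusted p = 0.00652) and 2.10 (SE 0.13, blocked adjusted p = 0.00652), with 3 of 8 members higher and 1 lower. Inflammatory fibroblast genes rose in 2 and fell in 4 of 13, Il6 by 1.41 (SE 0.11, blocked adjusted p = 0.00757) and the acute phase gene Saa3 by 2.69 (SE 0.23, blocked adjusted p = 0.00852) upward, Dpt by 2.31 (SE 0.17, blocked adjusted p = 0.00744) downward. NRF2 targets rose in 3 and fell in 7 of 19, with Gstm1 lower by -1.48 and Gsta3 by -1.27 (blocked adjusted p = 0.00652 and 0.0134). PPAR targets rose in 2 and fell in 5 of 15. Cemip, which breaks down hyaluronan, rose by 2.27 (SE 0.26, blocked adjusted p = 0.0129), with 3 of 6 hyaluronan genes higher and 1 lower. Matrix proteases and inhibitors rose in 4 and fell in 2 of 12, heat shock genes in 2 and 1 of 10, quiescence genes in 2 and 1 of 5, and interferon-stimulated genes fell in 2 of 9. The endothelial gene Tek fell by 2.35 (SE 0.19, blocked adjusted p = 0.00863) and the macrophage gene Lyz2 by 0.42 (SE 0.03, blocked adjusted p = 0.0109), the 1 member past the block among 7 immune and 9 macrophage markers. Schwann, pericyte and mesothelial markers rose in 1 and fell in 1 of 4, and the ductal, acinar and proliferation lists (1, 1 and 4 tested) had 0 past limma's blocked test.

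With the block 2285 of 7108 genes passed (1075 higher, 1210 lower), 259 by at least 2-fold. The blocked fit gave 2032 without a variance trend, and 1908 genes had a deposited adjusted p under 0.05. The planned fit, without the block, gave 4271 (1972 higher, 2299 lower), 280 by at least 2-fold. In the deposited tables same-numbered libraries had been adjusted to each other, and on simulated data with that adjustment the fit without the block called 323 unchanged genes, 62.6% of its calls, against 6 with the block. The blocked count was 632, 1592 and 0 without replicate 1, 2 and 3 of both groups (limma, with 2340 genes at an unadjusted p under 0.05 in the last), so each gene above loses its call there.

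PGD2 at the matched dose and time gave a smaller response in stellate cells, led by antioxidant genes. Hmox1 rose by 1.82 (SE 0.24, blocked adjusted p = 0.0346), from 6.78 ± 0.28 to 8.60 ± 0.41, Gsta3 by 2.24 (SE 0.25, blocked adjusted p = 0.0256) and Nqo1 by 1.72 (SE 0.21, blocked adjusted p = 0.03). The fatty acid binding gene Fabp4 rose by 1.62 (SE 0.11, blocked adjusted p = 0.00685). Acta2 differed by -0.43, from 8.20 ± 0.03 to 7.77 ± 0.10, and Actg2 by -0.72 (blocked adjusted p = 0.0316 and 0.0134).

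NRF2 targets rose in 17 of 19 with the block (18 without it, 18 adjusted over the list alone; camera adjusted p = 2.52e-10, or 0.59 with an estimated correlation). Cholesterol genes rose in 3 of 15 (10 higher and 1 lower without the block, 14 and 1 adjusted over the list alone; camera adjusted p = 0.000543, or 0.59 with an estimated correlation). Interferon-stimulated genes fell in 2 of 9 (7 without the block, 7 adjusted over the list alone; camera adjusted p = 0.0089, or 0.59 with an estimated correlation), Gbp2 by 0.42 (SE 0.05, blocked adjusted p = 0.0349). Myofibroblast genes rose in 1 and fell in 4 of 22 (5 and 9 without the block). PPAR targets rose in 4 of 15 and this set passed only with the block (adjusted p = 0.0346, and 0.076 without it), as did the stellate quiescence genes (0.0346 and 0.0587, and for both sets 0.59 with an estimated correlation), of which 0 of 5 members passed limma's blocked test and 3 rose without the block. Synthesis genes rose in 1 and fell in 1 of 11, Abcc4 by 1.10 (SE 0.14, blocked adjusted p = 0.0314) and the prostacyclin synthase Ptgis by 0.26 (SE 0.03, blocked adjusted p = 0.0417). Receptor genes passed in 0 of 5 with the block (1 higher and 3 lower without it), and Ptger4 differed by -0.19 (SE 0.04). Inflammatory genes rose in 2 and fell in 2 of 13, Il6 by 0.86 (SE 0.10, blocked adjusted p = 0.0301). Counts higher and lower were 2 and 0 of 8 for cAMP targets, 1 and 1 of 10 for heat shock, 0 and 1 of 12 for matrix proteases and 0 and 1 of 10 for TGF-beta targets. The imprinted RNA H19 fell by 2.59 (SE 0.28, blocked adjusted p = 0.0256) and Tek by 1.31 (SE 0.16, blocked adjusted p = 0.0314). No immune, macrophage, hyaluronan, proliferation or Schwann, pericyte and mesothelial marker passed limma's blocked test.

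With the block 548 of 7111 genes passed (282 higher, 266 lower), 35 by at least 2-fold. The blocked fit without a variance trend called 209, and 13 genes had a deposited adjusted p under 0.05. Without the block 2845 passed (1386 higher, 1459 lower), 46 by at least 2-fold and 1333 at adjusted p under 0.01, and 1792 without PGD2 replicate 3. On such simulated data the fit without the block called 294 unchanged genes. The blocked count was 1, 22 and 0 without replicate 1, 2 and 3 of both groups (limma, with 1571 genes at an unadjusted p under 0.05 in the last).

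PGE2 and PGD2 are isomers in which the keto and hydroxyl groups of the ring are exchanged, and their effects were compared gene by gene within replicate numbers, in a test added after the values were seen. Acta2 was higher with PGE2 by 2.06 (95% interval 1.71 to 2.42, adjusted p = 0.00681), Cnn1 by 2.12 (1.75 to 2.49), Serpine1 by 2.15 (1.69 to 2.60) and Cemip by 1.73 (1.21 to 2.24). Gsta3 was lower with PGE2, by -3.51 (-4.15 to -2.87, adjusted p = 0.00684), as were Hmox1 (-2.29, -2.74 to -1.84), the exporter Abcc4 (-1.40, -1.64 to -1.16) and Ptger4 (-1.03, -1.22 to -0.84). For other genes the isomers did not differ by this test, with an interval of -0.14 to 0.19 for Ptgs1, -0.11 to 0.14 for the chaperone Hspa8 and -0.07 to 0.39 for the collagen Col1a1. The interval of Ptgs2, 0.30 to 2.23, missed the threshold at adjusted p = 0.0786.

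**Figure D4:**
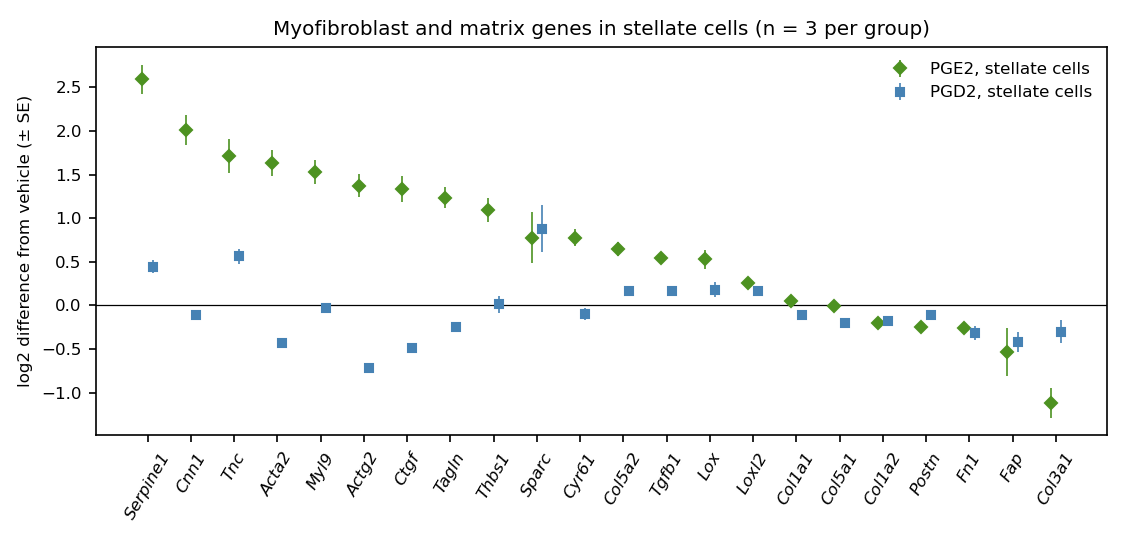
Log2 difference from vehicle (y axis, ± understated SE, n = 3 libraries per group) of the myofibroblast and matrix genes (x axis) in mPSC, with green diamonds for PGE2 and blue squares for PGD2. Acta2 lies at 1.63 with PGE2 and at -0.43 with PGD2.

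By list, NRF2 targets were lower with PGE2 than with PGD2 in 15 of 19 (18 adjusted over the list alone; camera adjusted p = 5.19e-07, or 0.61 with an estimated correlation). Myofibroblast genes were higher in 13 of 22 (14 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00136, or 0.603 with an estimated correlation), TGF-beta targets in 6 of 10 (7 adjusted over the list alone; camera adjusted p = 0.00173, or 0.603 with an estimated correlation) and matrix proteases and inhibitors in 6 of 12 (6 adjusted over the list alone; camera adjusted p = 0.0184, or 0.603 with an estimated correlation). PPAR targets were higher in 1 and lower in 8 of 15 (2 and 11 adjusted over the list alone; camera adjusted p = 0.00477, or 0.603 with an estimated correlation). Receptors were lower in 3 of 5 (3 adjusted over the list alone; camera adjusted p = 0.0215, or 0.603 with an estimated correlation) and cholesterol genes higher in 4 of 15 (5 adjusted over the list alone; camera adjusted p = 7.39e-05, or 0.66 with an estimated correlation). Of 7066 genes 1359 differed, 718 higher and 641 lower with PGE2, 143 by at least 2-fold and 231 at adjusted p under 0.01. Of the 5707 that did not pass, 4843 had a 95% interval within 0.5 of no difference on the log2 scale. Without replicate 1 the count was 0 (limma, with 1657 genes at an unadjusted p under 0.05), so every call named here ends, and without replicate 3 it was 370.

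Both isomers were measured against the same vehicle cultures, so their effects share chance values. With the block 380 genes were called the same way for both, 168 higher (41.7 for independent lists) and 212 lower (45.4), and 30 in opposite ways. Without it 1975 were shared, 894 higher (380 for independent lists) and 1081 lower (472), and 171 were opposite. Unchanged groups simulated against the same vehicles made 135 calls and shared 10.4 on average without the block. With it they made no calls in limma, so the blocked overlap had no simulated counterpart. The covariance of the effects was 0.0677, against 0.0144 in that simulation, with r = 0.615 and 0.472 across genes. Vehicles of 3 cannot be divided into separate controls of at least 2 each, so part of the excess may still come from the shared controls.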

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

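The tests of the 3 patterns weighed here were chosen after the results were seen, and so were the direct comparison of PGE2 with PGD2 and the count over all splits that part the BMM pairs, while the other counts over splits were planned.

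Tuft transcripts in 1 non-tuft library of the KC pancreas came first. In non-tuft replicate 1 Rgs13 stood at 7.74 and Gnat3 at 6.82, and the tuft marker list averaged 2.96 against 0.73 and 1.1 in the others. A tuft library under a wrong label is argued against by the islet genes Ppy, Pyy and Sst, whose mean lay 9.72 above the highest tuft library (SD of these 0.442). A few tuft cells of the sorted kind in the library cannot be told apart from tuft cells low in the sort protein: the 14 markers above the median level lay below the tuft libraries by unequal amounts (SD 1.42, and 1.29 without Siglecf, against 0.611 between tuft libraries), but few cells would scatter more than libraries of 100, and Siglecf, listed at 0 in 3 of the 3 non-tuft libraries, is fixed by the sort. A difference between the mice was not tested.

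NRF2 targets were higher with PGD2 in macrophages and in stellate cells. BMM, with no adjustment per replicate, had 17 of 19 higher with the block. As other cells they cannot tell whether that adjustment caused the mPSC rise. A stress response raising heat shock genes as much is argued against in mPSC (heat shock median 0.074, NRF2 targets 0.799) and in resting BMM (0.301 and 2.39), but after LPS (1.2 and 1.38) it cannot be told apart, since both lists rose alike. With PGE2, 15 of 19 were lower than with PGD2, which is consistent with an action of PGD2 that PGE2 lacks at this dose. As the pattern was found and tested on the same data, such an action remains a hypothesis.

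Proliferation genes fell with PGD2 in resting BMM and less so after LPS. If LPS had merely left values too near 0 to fall, members with room should have fallen by the same linear fold. That is a median of 0.815 on the log2 scale if 1 had been added before the log. Their median fall was -0.0109, a slight rise, and 7 of these 8 members (not Mcm5) fell short by over 2 SE. On a plain log scale 6 of 6 fell short. For the other 8 members, which had almost nothing left to lose (the list stood at a median of 0.912 after LPS and 5.72 before), the floor cannot be told apart from a missing effect. A changed PGD2 response or too few dividing cells after LPS may explain the members with room, but neither was tested.

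Between tissues, the tuft effect differed in 448 genes by the test of the difference. Values are the pancreatic minus the intestinal effect on the log2 scale. It was higher in the pancreas for Ugt1a7c (8.38), Gsta2 (8.19), Sprr2a3 (7.80), Ces2c (7.68) and Hpgd (4.22). It was lower for Krt23 (-9.30), Hmgn3 (-7.39), Sst (-7.10), Stra6l (-6.98), Pla2g4a (-3.85) and Ptgs1 (-2.93). Of these, Sst, Sprr2a3 and Hpgd had no library listed at 0, and the other differences are not exact. Without 1 library, calls were lost for Gsta2 (up to 0.0667, intestinal tuft replicate 1 or 2 and intestinal non-tuft replicate 1 or 3) and Sprr2a3 (up to 0.0533, pancreatic tuft replicate 1 or 2, intestinal tuft replicate 2 or 3 and intestinal non-tuft replicate 1). Pla2g4a and Ptgs1 were lost as given above (up to 0.0618 and 0.0811).

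The PGD2 effect in BMM differed with and without LPS in 2301 genes. Values are the effect after LPS minus that without. Higher were Tubb2b (3.99), Hmmr (3.55), Akap2 (3.22), Rgs1 (2.82), Hpgds (1.07) and Ptges3 (0.59). Lower were Ms4a4b (-4.16), Arg1 (-4.10), Pla2g7 (-3.73), Clec4n (-3.64), Ptges (-2.61), Ptgir (-2.19) and Ptger2 (-1.82). Libraries listed at 0 enter for Tubb2b, Akap2 and Ms4a4b, so their differences are not exact. The call of Akap2 was lost (up to 0.0915) without replicate 1, 2 or 3 of LPS PGD2 or vehicle, LPS vehicle replicate 1, or PGD2 replicate 1 or 3.

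Other splits of the same libraries were counted for each comparison with limma. For groups of 3 against 3 the 10 splits are too few for a share under 0.05, and 1 of the 10 splits, the real one, was as large in each. The real and highest other counts were 297 and 0 in the KC pancreas, 1960 and 0 in the intestine, 2901 and 1 for PGD2 in resting BMM, 5661 and 0 for LPS, 2166 and 2 for PGD2 after LPS, 4271 and 1 for PGE2 and 2845 and 10 for PGD2 in mPSC. Among the 3 other splits that part all 3 BMM pairs as the real one does, the highest were 1 for PGD2, 0 for LPS and 0 for PGD2 after LPS. For PGE2 against PGD2 the 4 sign patterns are too few as well (1359 real, 0 highest other). For the difference between the tissues, 6 of 100 splits gave at least 448 genes, the highest other 588, so chance was not excluded. The 5 others keep or swap the labels of 1 whole tissue and so hold real tuft effects, and the highest of 78 splits that mix labels in both tissues gave 1. For the PGD2 effects with and without LPS, 1 of 100 drawn splits, the real one with 2301 genes, was as large, with 1482 as the highest other (1125 among those parting the same pairs) and 3 among the 78 that mix both arms. As replicate numbers pair these libraries, all 32 splits that part the 6 pairs were counted too, and 2 were as large (a share of 0.0625), so chance was not excluded. The other one, with 3317 genes, swaps the labels of 1 whole arm and so holds real PGD2 effects, while the highest of the 18 that mix both arms gave 2. With the replicate block 2 of 32 were as large too (3689 real, 4574 highest other, 0 among the 18).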

How the results depend on the processing

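Fits without a variance trend, combinations with the replicate block, blocked fits leaving out a number and the PGE2 to PGD2 tests were chosen after the results were seen. No named gene reversed direction in any setting. Over all settings and named genes the verdict held 11058 times, was lost 1295 times and was gained 184 times. Of the counts, 116 stayed within 1.5 times their value and 55 did not, and the latter are among the values below. Why the block changed counts was not tested. With the replicate block the count was 182 in the KC pancreas, 3604 for PGD2 after LPS, 3689 for the PGD2 difference, 2285 for PGE2 and 548 for PGD2 in mPSC, and the shared calls were 380 in mPSC and 1303 in BMM. With the block and no variance trend it was 2032 and 209 in mPSC, and with the block and a 2-fold change 259 and 35. With a 2-fold change alone the counts were 698 for PGD2, 2058 for LPS, 394 for PGD2 after LPS and 701 for the difference in BMM, and 280, 46 and 143 for PGE2, PGD2 and their difference in mPSC. At adjusted p under 0.01 they were 59 in the pancreas, 948 in the intestine and 120 for the tissue difference. In BMM they were 1892, 1104 and 1196 (PGD2, PGD2 after LPS, difference), with 312 shared, and in mPSC 1333 for PGD2 and 231 for the isomers. Unchanged groups simulated in mPSC shared 10.4 of 135 calls on average.

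Leaving out 1 library gave 30 to 412 in the pancreas, 1113 to 1438 in the intestine, 200 to 516 for the tissue difference, 1792 to 2390 for PGD2 in mPSC and 0 to 1250 for the isomers (370 without replicate 3). With the block, leaving out replicate 1, 2 or 3 of both groups gave 632, 1592 and 0 for PGE2 and 1, 22 and 0 for PGD2. In limma, 2340 and 1571 genes had an unadjusted p under 0.05 in the settings with 0, and 1657 for the isomers. Of the list tests 5 of 52 passed with an estimated correlation. With the block 47 passed, against 45 of the same tests without it. Only intestinal Paneth markers (0.165 to 0.0373), PPAR targets (0.076 to 0.0346) and quiescence genes (0.0587 to 0.0346) with PGD2 in mPSC were gained. Only PPAR targets in resting BMM were lost (0.0451 to 0.128). In the tuft tables same-number correlations missed the pairing minimum (0.0174 to 0.0442 in the pancreas, -0.0117 to 0.0404 in the intestine). Yet 6 of 6 pancreatic libraries (3 of 6 intestinal) matched their own number best, so pairing is open. With the block the intestine gave 1685 and the tissue difference 355 (3 tuft markers in place of 7). Acinar calls went from 12 to 5 in KC and 9 to 5 for the difference. Not run, for lack of a use on log2 values, were another pseudocount and upper-quartile scaling, quantile normalization of the already normalised tuft and BMM tables, and block or weights for the isomers. The unknown depth limits what a value of 0 means.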

Other observations

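The overlap of PGD2 calls between cell types was chosen after the results were seen, and the values in this part come from no planned comparison.

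PGD2 was the one treatment given to both macrophages and stellate cells, at the same dose and for different times. Among 5690 genes tested in both, and with the replicate block, 135 rose in BMM and mPSC, where 56.4 would be shared by independent lists, and 34 fell in both (26.5). Another 39 were called in opposite directions. Shared rises included Hmox1 (4.23 in BMM, 1.82 in mPSC), Nqo1 (3.52 and 1.72), and the prostaglandin exporter Abcc4 (1.61 and 1.10). The mPSC calls end in the blocked fit without replicate 3 of both groups, which called 0 genes in limma (1571 at an unadjusted p under 0.05).

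The tables also show where prostanoid genes stood at rest. In vehicle-treated BMM, Ptgir stood at 2.58 ± 0.37, Ptger2 at 0.84 ± 0.23 and Ptges at 0.79 ± 0.22, and after LPS Ptges stood at 8.50 ± 0.28. In vehicle-treated mPSC, Ptger4 stood at 3.10 ± 0.14 and Ptgs2 at 2.41 ± 0.30 in the table with PGE2. Ptgds, the lipocalin-type prostaglandin D synthase, was listed at 4.03, 2.22 and 0 in the KC non-tuft and at 0, 0.33 and 0 in the KC tuft libraries, too low to be tested. Epcam, a gene of the sort, differed by 0.95 between KC tuft and non-tuft cells (SE 0.35, adjusted p = 0.221). In the intestine it differed by 0.85 (SE 0.21, adjusted p = 0.0265), a call lost without tuft replicate 1, 2 or 3 (0.0874, 0.138 and 0.0658) or non-tuft replicate 1 or 3 (0.0712 and 0.0693).

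In the deposited adjusted p-values, 179 genes of the pancreatic table were under 0.05 (109 higher and 70 lower in tuft cells), 1508 of the intestinal table (769 and 739), 1908 of the PGE2 table (904 and 1004) and 13 of the PGD2 table (7 and 6).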
